A study of Mus musculus with 2 samples.

How the data were processed

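Total RNA was taken from 1 culture each of the MS-1 and SVEC4-10 lines, grown for 3 to 5 days to confluence and used up to passage 5 at a split of 1 to 6, per the labels' protocols. RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 µg of total RNA and hybridised to Affymetrix arrays, per the labels' protocols. The deposited values are probe set intensities on a linear scale, with 1 value per probe set and array. The summary method and its software are not given in the sources used here. The deposited intensities ran from 0.0937 to 14783 on the MS-1 array and from 0.0687 to 13509 on the SVEC4-10 array. Both arrays had a 2%-trimmed mean of 150.001, so each array had been scaled by 1 factor to a common target, and the values were used as deposited. A scaling of this kind assumes that the total signal of both lines is equal, and all ratios would shift together if it were not.

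Probe sets were named through the platform annotation and updated by gene identifier to the RefSeq table of assembly GRCm38.p6, which was used for names only. Of 45101 probe sets, 64 were controls, 34945 had 1 gene (34741 matched to the RefSeq table), 932 had several genes and were left out, and 9160 were unnamed here. Of the unnamed probe sets, 74 were at least 4-fold higher on the SVEC4-10 array and 42 on the MS-1 array. Background was the 95th percentile of 129 probe sets of olfactory, vomeronasal and taste receptor and keratin-associated protein genes. Of the probe sets with 1 gene, 59.6% were above background on the MS-1 array and 58.5% on the SVEC4-10 array. Each value was raised to the background of its array before the log2 ratio was taken, so a ratio against background is a lower bound. A gene was measured if above background on at least 1 array, and was represented by the probe set with the highest mean log2 signal, avoiding the cross-hybridising class where another existed. Of 79 named genes with several measured probe sets, 26 had probe sets over 2 log2 units apart, and 18 of the genes at least 2-fold apart had a probe set under 2-fold or of the other sign. For these genes the ratio of a further probe set, or the range, is given.

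Control probe sets were compared between the arrays. The 3'/5' signal ratio was 0.809 and 0.812 for Gapdh and 1.22 and 1.27 for beta-actin on the MS-1 and SVEC4-10 arrays. Hybridisation controls (18 probe sets) had a SVEC4-10 over MS-1 ratio of 0.961. Poly-A control transcripts (21 probe sets) were 1.43-fold higher on the SVEC4-10 array, with log2 ratios from 0.28 to 0.89. The number of arrays limits the precision.

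No test between the lines was possible. Genes were counted by size, at least 4-fold apart, and the error of a log2 ratio was estimated as the standard deviation of the difference between 2 probe sets of one gene, divided by the square root of 2. The named genes were the 12 with the largest log2 ratio in each direction whose other measured probe sets had the same sign, up to 4 members of each list with the largest absolute ratio, and 24 fixed genes. For each of 36 gene lists, the median log2 ratio was given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Of 1237 listed names, 1129 (91.3%) were found on the array. Medians of 20 lists lay outside the central 95% of random lists, 12 above and 8 below. Chance would give 1.8 if the genes of a list varied independently, as in the random lists. Genes of a real list can vary together, so more lists could fall outside without a difference between the lines. Some genes are in several lists, so the lists are not independent. Such percentiles describe these arrays and say nothing about variation between cultures. The groups, the counting rules, the gene lists, the named-gene rule and the alternatives were fixed before the data were examined, except scaling to the poly-A controls and the second marker lists, which were chosen afterwards.

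The alternatives were quantile normalization, centring on the median of expressed probe sets, scaling to the poly-A controls, background at the 40th percentile of all probe sets, no background floor, a doubled background, the mean over probe sets, leaving out probe sets of the less specific classes, the probe set with the smallest ratio, and thresholds of 2-fold and 8-fold. The steps were tested on simulated arrays with the spread found here (12086 genes). With no change put in, 0 genes were at least 4-fold apart and 415 at least 2-fold apart. The simulated error was normal and of 1 size for all probe sets. The error found here varied with signal (0.59 to 0.37) and had wider tails (0.49, or 0.36 from the median deviation). These counts therefore do not give the number of false differences in the data. Of genes changed by a log2 of 1.5, 3 and 4, 8%, 97% and 100% were recovered at 4-fold, a standard deviation of 0.49 was recovered as 0.48, and 4% of 200 unchanged lists fell outside the central 95%. Those lists were random draws of 30 genes with independent error, so their share was close to the expected one by construction. It cannot show how lists of genes that vary together behave. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.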

Results

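Gene expression was compared between a pair of mouse endothelial cell lines, MS-1, which derives from the small vessels of the pancreas, and SVEC4-10, which derives from an axillary lymph node. Both lines were immortalised with the SV40 large T antigen. The series holds 1 Affymetrix array per line, so there are no replicates, no difference between the lines has a replicate check, and no p-value was computed. The comparison asks which genes the 2 lines express at different levels when grown to confluence under routine culture. The media differed in serum, 5% fetal calf serum for MS-1 and 10% for SVEC4-10, so serum and line cannot be told apart. Each array gave a signal for 45101 probe sets, with a median of 18.7 on the MS-1 array and 18.4 on the SVEC4-10 array. Background, taken from probe sets of odorant, pheromone and taste receptor and hair keratin-associated genes, lay at a signal of 16.3 and 17.6. Of 18193 genes, 12457 were above background on at least 1 array: 10127 on both, 1303 on the MS-1 array only and 1027 on the SVEC4-10 array only.

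The array labelled SVEC4-10 carried little signal for genes that define endothelium and high signal for many mesenchymal and interferon-response genes, whereas the MS-1 array showed the reverse for endothelial genes. Pecam1, which encodes the endothelial adhesion molecule CD31, had a signal of 4777 on the MS-1 array and was below background on the SVEC4-10 array, a difference of at least 271-fold. Dcn, which encodes the collagen-binding proteoglycan decorin, had a signal of 7363 on the SVEC4-10 array and was below background on the MS-1 array, a difference of at least 453-fold. A fold written as "at least" compares a signal with the background level of the other array, and log2 ratios are of SVEC4-10 over MS-1. At least 4-fold differences were found for 705 genes with higher signal on the SVEC4-10 array, 331 of them at background on the MS-1 array. The corresponding number with higher signal on the MS-1 array was 528, of which 254 were at background on the SVEC4-10 array. The share of these genes that were higher on the SVEC4-10 array was 57.2%, against 37.1% (493 and 836 genes) when the arrays were scaled to the poly-A control transcripts added to the RNA, which lowers every log2 ratio by 0.51. That scaling lowers random lists by the same amount, so it changes the sign of some list medians but not their percentiles.

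The error of a log2 ratio, as the standard deviation between probe sets of the same gene, was 0.49 (4407 genes). This estimate holds no variation between cultures and no error shared by all probe sets of an array, such as one of scaling. Differences between the transcript regions probed also enter. The error fell with signal, from 0.59 for the dimmest 1469 genes to 0.37 for the brightest 1469. Where a gene at least 4-fold apart had several measured probe sets, the probe sets gave the same direction for 342 of 357 genes higher on the SVEC4-10 array and for 250 of 267 genes higher on the MS-1 array. Across genes above background on both arrays, log2 signals had a Pearson r of 0.83 and a Spearman rho of 0.83, where genes are not independent replicates.

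**Figure D1:**
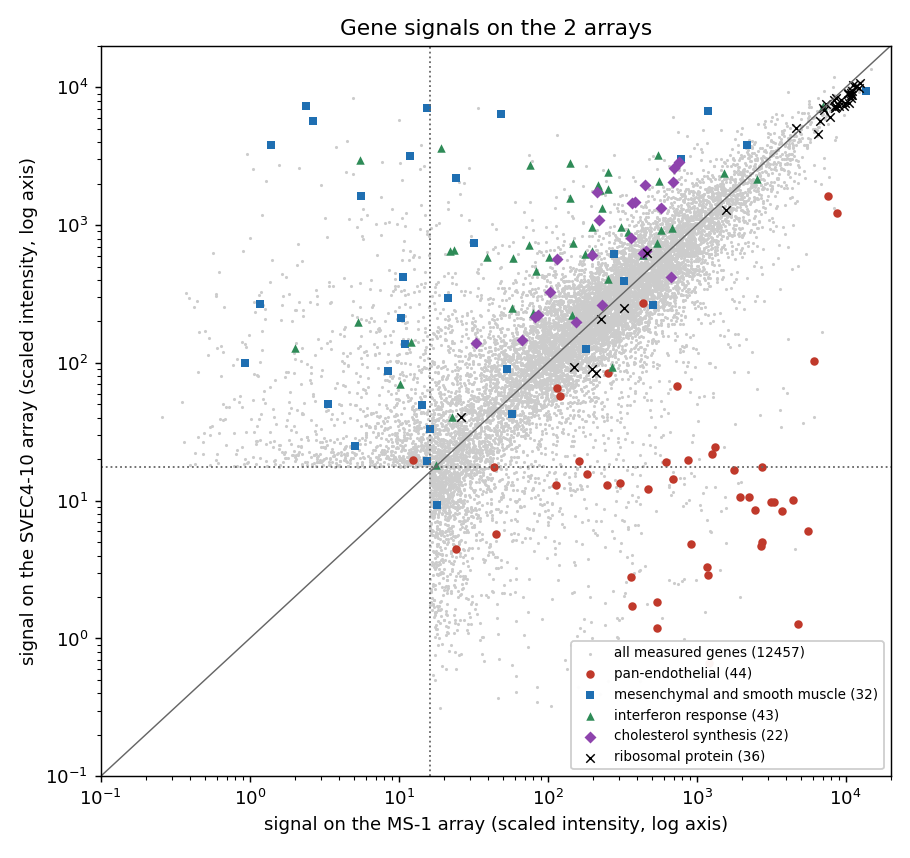
Signal of each of 12457 measured genes on the MS-1 array (horizontal log axis, scaled intensity) and on the SVEC4-10 array (vertical log axis), 1 point per gene, with dotted lines at each array's background, a diagonal of equal signal, and 5 gene lists in colour. Points are drawn at the signals before they were raised to background. With values raised to background, 40 of 44 pan-endothelial genes were at least 2-fold higher on the MS-1 array. By the same count, 22 of 32 mesenchymal and smooth muscle genes were at least 2-fold higher on the SVEC4-10 array.

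The 12 genes with the largest difference towards MS-1 came mostly from the pan-endothelial list. Emcn, an endothelial sialomucin, had a signal of 5568 on the MS-1 array and was at least 316-fold higher there. It was followed by Pecam1, by Prom1, the stem cell antigen CD133, at least 261-fold higher, and by Nos3, the endothelial nitric oxide synthase, at least 253-fold higher. Ch25h, which hydroxylates cholesterol, was at least 220-fold higher (signal 3878) and Myct1 at least 214-fold higher. Adgrf5, an adhesion receptor, Ramp2, a partner of the calcitonin receptor-like receptor, Esam and Icam2, both endothelial adhesion molecules, and Thbd, the thrombin receptor thrombomodulin, were at least 187-, 180-, 155-, 154- and 155-fold higher on the MS-1 array. The probe set of smallest ratio gave -2.58 for Adgrf5 and -4.48 for Myct1. Apln, the peptide ligand apelin, was above background on both arrays, with signals of 6093 and 40.8, a 149-fold difference.

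The 12 genes with the largest difference towards SVEC4-10 were led by Upk3b, a uroplakin that is also found on mesothelium, with a signal of 8335 and a difference of at least 512-fold. A second uroplakin, Upk1b, was at least 227-fold higher, with a lowest log2 ratio of 5.33 among its probe sets. Col1a2, Col5a2, Col1a1 and Col3a1, which encode chains of fibrillar collagens, were at least 438-, 354-, 349.9- and 196-fold higher on the SVEC4-10 array, although 1 further probe set of Col1a2 gave a log2 ratio of only 0.39 and the second of Col3a1 gave 4.25. Gas1, a growth arrest gene, was at least 250.4-fold higher, with a lowest log2 ratio of 0.81 among its 3 probe sets. Ptgis, the prostacyclin synthase, Tagln, the contractile protein transgelin, and Aldh1a1, a retinaldehyde dehydrogenase, were at least 234-, 234- and 203-fold higher. Bgn, the proteoglycan biglycan, had signals of 34.0 and 7101, a 209-fold difference.

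Of 50 pan-endothelial genes, 44 were measured, and 40 of these were at least 2-fold higher on the MS-1 array, 0 on the SVEC4-10 array and 4 on neither. Their median log2 ratio was -5.16, lower than that of any of 10000 random lists of the same size and expression level. For a list outside the central 95% of random lists whose median moved by over 1.5 times in an alternative processing, the range over the alternatives is given, relative to all genes. Among the endothelial genes fixed in advance, Kdr, the main receptor for vascular endothelial growth factor, had signals of 1268 and 21.9, a 57.9-fold difference. Eng, the co-receptor endoglin, was 53.8-fold higher on the MS-1 array, Tek, the angiopoietin receptor, at least 17.4-fold and Cdh5, the endothelial cadherin, at least 14.1-fold, with a log2 ratio of -6.16 at its second probe set. Cd34 had signals of 6115 and 103. Smaller differences were found for Flt1, whose signals of 115 and 65.3 gave a log2 ratio of -0.81 with an error of 0.49 and whose 4 probe sets ranged from -1.67 to -0.81, and for Vwf, the von Willebrand factor, which barely exceeded background on the MS-1 array (signal 24.2) and did not on the other.

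Lists of endothelial subtypes held genes that differed in both directions. Of 20 measured arterial and Notch genes, 10 were at least 2-fold higher on the MS-1 array and 4 on the SVEC4-10 array, with 6 on neither (median -0.96, percentile 0.010 of the random lists, from -1.72 with background doubled to -0.34 with background at the 40th percentile of all probe sets). Notch4, the endothelial Notch receptor, Nrarp, a Notch target, and Cxcr4, a chemokine receptor, were at least 65.3-, 51.9- and 48.2-fold higher on the MS-1 array, although the second probe set of Notch4 gave a log2 ratio of -0.90. Igfbp3 was at least 51.5-fold higher on the SVEC4-10 array. Of 16 sinusoidal and fenestrated genes, 10 were higher on the MS-1 array and 3 on the SVEC4-10 array (3 on neither, median -1.64, lower than any random list, range -2.09 to -0.98). Among these, Plvap, which forms the diaphragm of fenestrae, was at least 66.7-fold higher on the MS-1 array, Stab1, a scavenger receptor, 51.6-fold and Ptprb, an endothelial phosphatase, at least 26.8-fold, with a smallest log2 ratio of -1.25 among its 3 probe sets. Plvap and Ptprb, with Cav1, are also in the pan-endothelial list.

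The lymphatic list did not lie apart from random lists: 9 of 21 measured genes were higher on the SVEC4-10 array, 5 on the MS-1 array and 7 on neither, and the median of 0.29 (percentile 90.8) turned to -0.22 when scaled to the poly-A controls. It was 1.03 with background doubled and 0.048 with background at the 40th percentile of all probe sets. Prox1, the transcription factor that specifies lymphatic endothelium, was not above background on either array. Lyve1, a hyaluronan receptor of lymphatic and sinusoidal endothelium, was at least 70.9-fold higher on the MS-1 array, where its signal was 1249.7. Flt4, the receptor for lymphatic growth factors, was 2.14-fold higher on the MS-1 array. Pdpn, podoplanin, had signals of 228 and 1693, 7.43-fold higher on the SVEC4-10 array, and Maf was at least 146-fold higher there by the probe set used, with log2 ratios from 1.35 to 7.19 among its 6 probe sets. Angpt2, an antagonist of the Tek receptor, was 108-fold higher on the MS-1 array, but its second probe set gave a log2 ratio of -0.0099. Venous and high endothelial venule genes also lay within the random range (17 measured, 3 higher on the SVEC4-10 array, 7 on the MS-1 array and 7 on neither, median -0.43, percentile 3.38), with a median of -0.018 when background was doubled. Il33, a nuclear cytokine, was at least 22.2-fold higher on the SVEC4-10 array. Glycam1, a ligand of L-selectin in lymph node venules, was not above background on either array, and Madcam1 had a signal of 21.1 on the MS-1 array and was below background on the other. Ccl21a and Ddx3y were not analysed here, since no probe set was assigned to either gene alone.

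Molecules that hold leukocytes and cell junctions were lower on the SVEC4-10 array in 12 of 31 measured cases, higher in 3 and within 2-fold in 16 (median -0.54, percentile 0.030, range -0.59 to -0.17). Among the 12 were Pecam1, Cdh5, Esam, Icam2 and Cd34, which are also in the pan-endothelial list. Selp, P-selectin, had signals of 2548 and 64.7 and was 39.4-fold higher on the MS-1 array. Sele, E-selectin, had a signal of 211 on the MS-1 array and was below background on the other, and Icam1 had signals of 213 and 19.4. Vcam1 did not follow this difference: its signals of 1226 and 1418 gave a log2 ratio of 0.21, which is within the error of 0.49 and becomes -0.30 when scaled to the poly-A controls. Of 16 measured integrin subunits, 7 were higher on the MS-1 array, 5 on the SVEC4-10 array and 4 on neither (median -0.53, percentile 1.11, range -0.84 to -0.13). Itgb3, Itga4 and Itga6 were at least 19.1-fold, at least 13.6-fold and 6.22-fold higher on the MS-1 array, and Itgb5 was 27.2-fold higher on the SVEC4-10 array. The smallest log2 ratios among the probe sets of Itgb3 and Itga4 were -1.98 and -1.20.

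**Figure D2:**
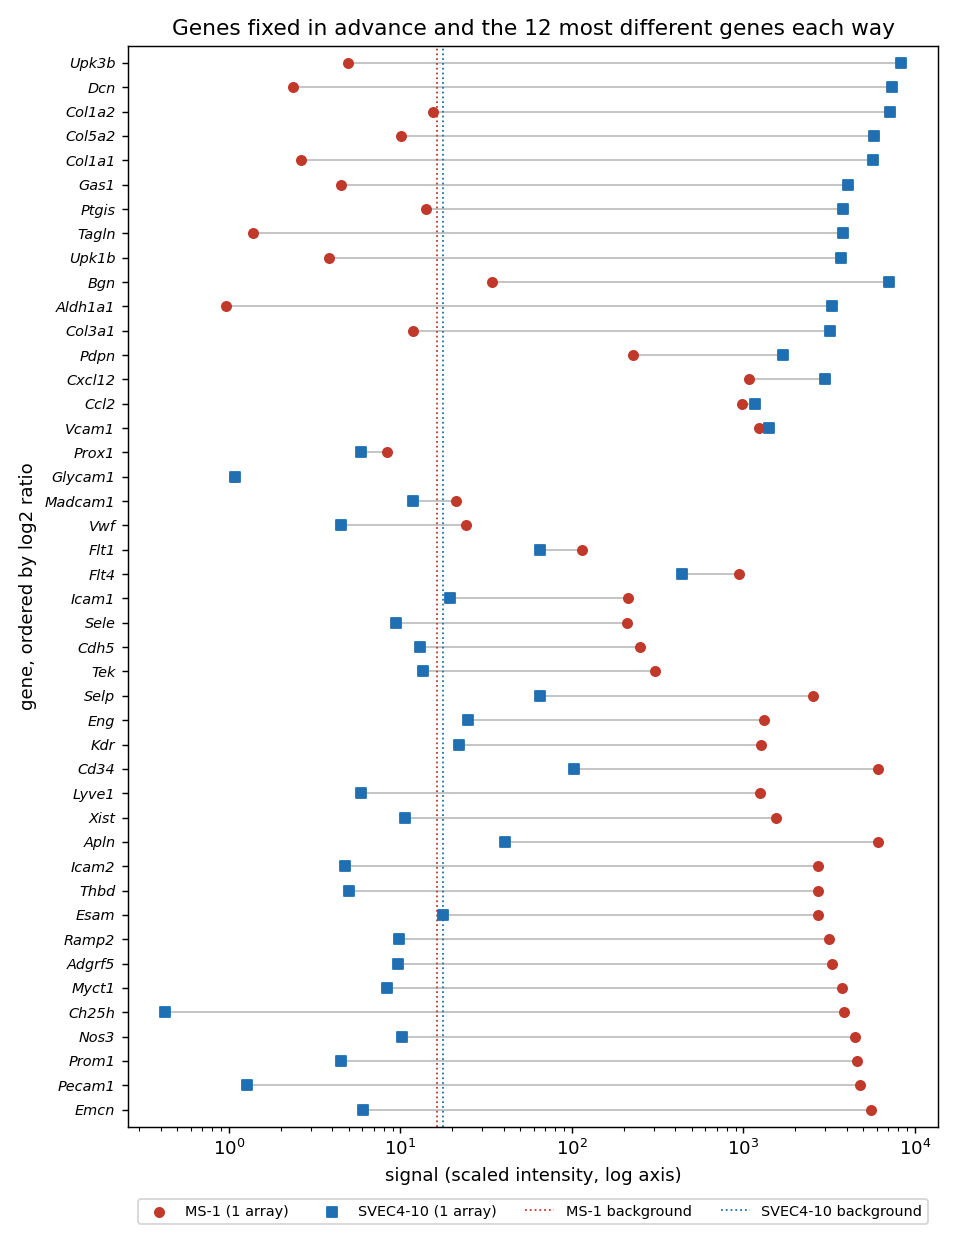
Signal on the MS-1 array (circles) and on the SVEC4-10 array (squares) on a log axis in scaled intensity units, for the genes fixed in advance and the 12 genes with the largest difference each way, ordered by log2 ratio, with dotted lines at each array's background. The squares of Emcn, Pecam1 and Nos3 lie below background at the bottom of the plot, the circles of Upk3b, Dcn and Col1a2 lie below background at the top, and Vcam1 and Ccl2 have nearly equal signals.

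Most measured mesenchymal and smooth muscle genes were higher on the SVEC4-10 array. Of 32 measured members of 40 listed, 22 were at least 2-fold higher there, 0 on the MS-1 array and 10 on neither, and the median log2 ratio of 2.46 (range 1.55 to 3.51) exceeded that of every random list. The other 8 members were not above background on either array and do not enter the median, among them (named after their values were seen) the smooth muscle genes Myh11, Cnn1, Myl9 and Lmod1, the pericyte gene Rgs5 and the fibroblast genes Thy1 and Fap. The list marks fibroblasts, pericytes and smooth muscle, and the direction of its measured genes was opposite to that of the pan-endothelial genes (median -5.16). In the basement membrane and matrix list, 14 of 36 genes were higher on the SVEC4-10 array, 5 on the MS-1 array and 17 on neither, with a median of 0.51 (percentile 99.9) that became -0.0031 when scaled to the poly-A controls. Fbln2, a fibulin, and Lox, which cross-links collagen, were at least 177- and 166-fold higher on the SVEC4-10 array. Matrix proteases and inhibitors lay within the random range (28 measured, 11 higher on the SVEC4-10 array, 6 on the MS-1 array and 11 on neither, median 0.16, percentile 84.1, or -0.35 when scaled to the poly-A controls). Within that list, Serpinf1, an inhibitor of angiogenesis, and the collagen- and matrix-degrading enzymes Mmp13 and Mmp3 were at least 64.4-, 63.2- and 51.0-fold higher on the SVEC4-10 array, and Adamts4, an aggrecan protease, was 19.7-fold higher on the MS-1 array.

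Markers of other cell types gave no common direction. Of 13 measured epithelial genes, 4 were higher on the SVEC4-10 array, 3 on the MS-1 array and 6 on neither, with a median of -0.18 and a mean of 0.14 (percentile 20.9). Krt7 and Cdh3 were at least 12.5-fold and 7.08-fold higher on the SVEC4-10 array, and Krt18 and Krt19, other simple epithelial keratins with Krt7, were 8.21-fold and at least 6.85-fold higher on the MS-1 array. Of 10 measured leukocyte genes, 0 were higher on the SVEC4-10 array, 3 on the MS-1 array and 7 on neither (median -0.42, percentile 5.87). The 3 were Cd68, a lysosomal glycoprotein (signals 3645 and 45.9), Lcp1, an actin-bundling protein, at least 12.1-fold, and Coro1a, at least 2.88-fold but with a second probe set at a log2 ratio of -0.37, while Laptm5 was close to background (signal 26.1 on the MS-1 array). Of 7 measured pancreas genes, 1 was higher on the SVEC4-10 array and 6 on neither (median 0.13, percentile 62.4, and -0.39 when scaled to the poly-A controls). That gene was Cela1, an elastase, with a signal of 85.7, and Prss2, Cel and Ppy stayed at signals under 28.0. Of 8 measured fat cell genes, 2 were higher on the SVEC4-10 array, 1 on the MS-1 array and 5 on neither (median -0.27, mean 0.10, percentile 16.7). Lpl, a lipase, was at least 52.2-fold and Lipe 2.09-fold higher on the SVEC4-10 array, Fabp4, a fatty acid carrier also made by endothelium, was at least 23.7-fold higher on the MS-1 array, and Scd1 had a log2 ratio of -0.75.

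Interferon-response genes formed a further group with higher signal on the SVEC4-10 array. Of 43 measured members, 31 were at least 2-fold higher there, 1 on the MS-1 array and 11 on neither, and the median of 2.32 exceeded that of every random list. Ifi27l2a had signals of 19.4 and 3623, a 187-fold difference, and Ifi202b, a DNA-binding protein of the same response, was at least 184-fold higher. Usp18, which removes the ubiquitin-like modifier ISG15, was 35.9-fold and Oas2, an antiviral oligoadenylate synthetase, 29.7-fold higher. Of 10 measured leukocyte genes, 0 were higher on the SVEC4-10 array, while the mesenchymal list had a median of 2.46 there. Antigen presentation genes differed less: 4 of 18 were higher on the SVEC4-10 array, 1 on the MS-1 array and 13 on neither, and the median of 0.47 (percentile 97.6) became -0.047 when scaled to the poly-A controls. Psmb9, an immunoproteasome subunit, Tapbp, which loads peptides, and Cd1d1 were 5.85-, 5.14- and 4.19-fold higher on the SVEC4-10 array, and Cd274, the ligand PD-L1, was 2.52-fold higher on the MS-1 array.

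Among chemokines, 9 of 22 measured genes were higher on the SVEC4-10 array, 3 on the MS-1 array and 10 on neither, and the median of 0.51 (percentile 99.2) became -0.0026 when scaled to the poly-A controls, with a range of 0.0022 to 0.76 relative to all genes. Ccl7 was at least 12.1-fold, Cxcl10, an interferon-induced chemokine, 11.2-fold, Cxcl15 at least 5.24-fold and Ccl5 4.97-fold higher on the SVEC4-10 array, but the second probe set of Cxcl15 gave a log2 ratio of 0.46, within the error. Ccl2, with signals of 985 and 1171, gave a log2 ratio of 0.25, within the error of 0.49 and -0.26 when scaled to the poly-A controls. The 3 probe sets of Cxcl12 disagreed, the lowest log2 ratio being -2.20, while the probe set used had signals of 1073 and 2986, so no direction is given. Cytokines and colony stimulating factors lay within the random range (21 measured, 5 higher on the SVEC4-10 array, 3 on the MS-1 array and 13 on neither, median 0.062, percentile 60.3, and -0.45 when scaled to the poly-A controls). Il18 was 13.6-fold and Tgfb3 24.0-fold higher on the SVEC4-10 array, and Il15 was at least 5.40-fold higher on the MS-1 array. The NF-kB response list was balanced, with 7 of 29 genes higher on each array and 15 on neither (median 0.21, percentile 83.7, and -0.30 when scaled to the poly-A controls). Saa3 and Ptx3, both acute-phase proteins, were 12.4-fold and at least 10.3-fold higher on the SVEC4-10 array, while Ptgs2, the inducible cyclooxygenase, was 12.2-fold higher on the MS-1 array.

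Genes of cholesterol synthesis and its control were higher on the SVEC4-10 array in 17 of 22 measured cases, higher on the MS-1 array in 0 and within 2-fold in 5, with a median of 1.59 above every random list. Idi1, the isopentenyl diphosphate isomerase, had signals of 215 and 1729, an 8.06-fold difference. Lss, which makes lanosterol, Nsdhl, a later enzyme, and Sqle, the squalene epoxidase, were 4.96-, 4.92- and 4.37-fold higher, with log2 ratios from 0.42 to 3.48 among the 3 probe sets of Lss. The SVEC4-10 culture had received 10% serum and the MS-1 culture 5%, and the S phase genes had a median of 0.23 (-0.28 when scaled to the poly-A controls).

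The TGF-beta and BMP, Wnt and angiogenic lists had medians above 0, and the YAP and serum response list a median below 0. Of 32 TGF-beta and BMP genes, 15 were higher on the SVEC4-10 array, 5 on the MS-1 array and 12 on neither (median 0.85, above every random list, from 0.34 with the probe set of smallest ratio to 1.01). Id3, a BMP target, and Bmpr1a, a BMP receptor, were at least 73.1- and 20.3-fold higher on the SVEC4-10 array, with log2 ratios from 0.89 to 5.84 among the 5 probe sets of Bmpr1a, and Fst, the activin antagonist follistatin, was 57.6-fold higher on the MS-1 array. Of 20 Wnt genes, 9 were higher on the SVEC4-10 array, 1 on the MS-1 array and 10 on neither (median 0.72, percentile 99.5). The receptors Fzd1, Fzd7 and Fzd2 were at least 62.8-fold, 7.91-fold and 7.44-fold higher on the SVEC4-10 array, and the ligand Wnt4 had a signal of 179.7 there and was below background on the MS-1 array. The second probe sets of Fzd1 and Fzd7 gave log2 ratios of 2.99 and 0.81. Among 48 angiogenic growth factors and receptors, 19 were higher on the SVEC4-10 array, 14 on the MS-1 array and 15 on neither (median 0.55, percentile 99.9, range 0.31 to 0.79). Igfbp7 was at least 132-fold higher on the SVEC4-10 array, with a second probe set at a log2 ratio of 1.56, and S1pr1, the sphingosine phosphate receptor of vessels, was at least 108-fold higher on the MS-1 array. The YAP and serum response list lay below every random list (28 measured, 9 higher on the SVEC4-10 array, 11 on the MS-1 array and 8 on neither, median -0.63). Fosl1, Klf2 and Crim1 were 20.1-, 19.7- and 11.7-fold higher on the MS-1 array, with a second probe set of Crim1 at a log2 ratio of -0.97, whereas Axl, a receptor tyrosine kinase, was at least 128-fold higher on the SVEC4-10 array.

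**Figure D3:**
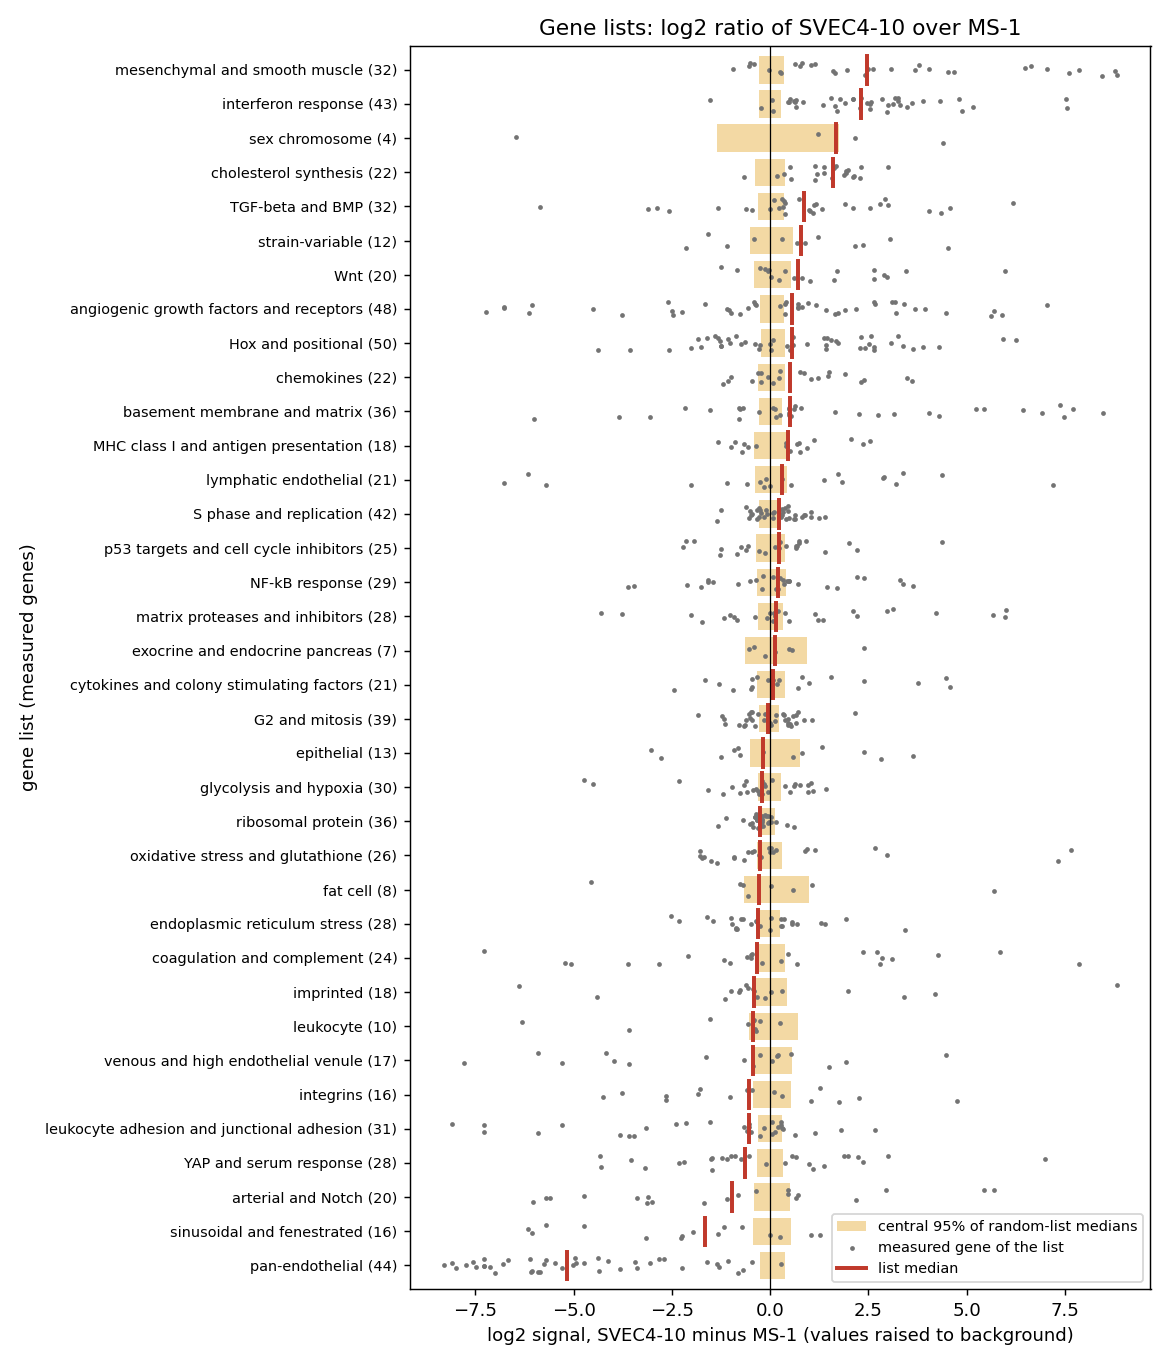
Log2 ratio of SVEC4-10 over MS-1 (horizontal axis, values raised to background) for the measured genes of the 36 lists (grey points), with the list median (red bar) and the central 95% of medians of 10000 random lists matched on size and expression (shaded). The medians run from -5.16 for the pan-endothelial list to 2.46 for the mesenchymal and smooth muscle list, and 20 of 36 lists fall outside their shaded range. Scaling to the poly-A controls lowers every point by 0.51, which turns the medians of the lymphatic, chemokine, cytokine, antigen presentation, NF-kB, basement membrane, matrix protease, pancreas, S phase and p53 lists below 0 and moves the random range equally.

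Genes that mark position and lineage differed in both directions. Of 50 measured Hox and other positional transcription factors, 22 were higher on the SVEC4-10 array, 14 on the MS-1 array and 14 on neither (median 0.55, percentile 99.8, range 0.11 to 0.69). Wt1, which is expressed in mesothelium, kidney and gonad, had a signal of 1233 on the SVEC4-10 array and was at least 75.8-fold higher there. Gata6 and Tbx18 were at least 60.9- and 19.5-fold higher on the SVEC4-10 array, with log2 ratios from 1.20 to 5.93 among the 3 probe sets of Gata6, and Hoxd10 was at least 20.9-fold higher on the MS-1 array. Among 18 imprinted genes, 4 were higher on the SVEC4-10 array, 3 on the MS-1 array and 11 on neither, with a median of -0.41 (percentile 1.57, range -0.61 to -0.16) and a mean of 0.10. Mest was at least 83.1-fold higher on the MS-1 array and Peg3 18.4-fold higher on the SVEC4-10 array. Ndn was 21.3-fold higher on the MS-1 array by the probe set used, but its 6 probe sets ranged from -5.32 to 0.11. All 4 measured sex chromosome genes differed: Xist, the RNA that silences an X chromosome in female cells, had signals of 1554 and 10.6 (smallest log2 ratio of its 3 probe sets -1.63), and the Y-linked Eif2s3y, Uty and Kdm5d were at least 21.0-, 4.44- and 2.33-fold higher on the SVEC4-10 array (list median 1.68, mean 0.33, percentile 97.1). Among 12 genes known to vary between mouse strains, 5 were higher on the SVEC4-10 array, 3 on the MS-1 array and 4 on neither (median 0.78, percentile 99.4, range 0.27 to 0.96). Wdfy1, Fv1 and Pttg1 were 8.22-, 5.17- and 4.46-fold higher on the SVEC4-10 array, with log2 ratios from 0.79 to 3.79 among the 4 probe sets of Wdfy1, and the 2 probe sets of Hddc3 gave log2 ratios of -0.16 and 4.53.

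Proliferation genes differed little. Of 42 S phase and replication genes, 36 were within 2-fold, 4 higher on the SVEC4-10 array and 2 on the MS-1 array, and their median of 0.23 (percentile 97.8, range 0.072 to 0.24) became -0.28 when scaled to the poly-A controls. Prim1 and Rfc4 were 2.63- and 2.37-fold higher on the SVEC4-10 array, and Rrm2 and Pole 2.55- and 2.36-fold higher on the MS-1 array. Of 39 G2 and mitosis genes, 33 were within 2-fold, 2 higher on the SVEC4-10 array and 4 on the MS-1 array (median -0.047, percentile 48.3). The largest difference was that of Pttg1, securin, which was 4.46-fold higher on the SVEC4-10 array. Nuf2, Ube2c and Kif23 were 3.55-, 2.34- and 2.27-fold higher on the MS-1 array, with a second probe set of Kif23 at -0.97. The p53 targets and cell cycle inhibitors lay within the random range (25 measured, 4 higher on the SVEC4-10 array, 5 on the MS-1 array and 16 on neither, median 0.22, percentile 85.8, and -0.30 when scaled to the poly-A controls). Cdkn2a, an inhibitor of cyclin-dependent kinases, was at least 20.7-fold and Sesn1 4.62-fold higher on the SVEC4-10 array, while Cdkn1a, the inhibitor p21, and Zmat3 were 4.66- and 4.40-fold higher on the MS-1 array. Of 36 ribosomal protein genes, 34 were within 2-fold, 0 were higher on the SVEC4-10 array and 2 on the MS-1 array (median -0.25, percentile 5.67). Rps27 and Rps24 were 2.51- and 2.18-fold higher on the MS-1 array, the smallest log2 ratio of the 5 probe sets of Rps24 was -0.21, Rpl12 had a log2 ratio of -0.70, and the 4 probe sets of Rps20 ranged from -0.43 to 0.62.

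The glycolysis and hypoxia, oxidative stress and endoplasmic reticulum stress lists lay within the random range. Of 30 glycolysis and hypoxia genes, 22 were within 2-fold, 3 higher on the SVEC4-10 array and 5 on the MS-1 array (median -0.21, percentile 11.5). The 4 with the largest ratios were all higher on the MS-1 array: Adm, the vasodilator adrenomedullin, at least 26.5-fold, Egln3, an oxygen-sensing hydroxylase, 22.8-fold, Slc2a1, the glucose transporter GLUT1, 4.97-fold and Aldoa 2.98-fold, with a smallest log2 ratio of -0.60 among the 5 probe sets of Aldoa. Of 26 oxidative stress and glutathione genes, 5 were higher on the SVEC4-10 array, 6 on the MS-1 array and 15 on neither (median -0.26, mean 0.37, percentile 6.77). Gsta4, a glutathione transferase, was at least 159-fold higher on the SVEC4-10 array, Sod3 at least 7.81-fold and Gstt1 at least 6.38-fold. Of 28 endoplasmic reticulum stress genes, 4 were higher on each array and 20 on neither (median -0.30, percentile 3.60). Vldlr, a lipoprotein receptor, was at least 10.8-fold higher on the SVEC4-10 array by the probe set used, but its 6 probe sets ranged from 0.26, within the error, to 3.71. Nupr1 was 3.84-fold higher on the SVEC4-10 array, and Trib3 and Atf3 were 5.74- and 4.95-fold higher on the MS-1 array. Coagulation and complement genes lay below the central 95% of random lists but divided evenly, with 8 of 24 higher on each array and 8 on neither (median -0.33, percentile 2.33, mean 0.11), and the median relative to all genes ranged from -0.49 to 0.054, the latter with background doubled. C1s1, a complement protease, was 57.2-fold higher on the SVEC4-10 array, and F8, coagulation factor VIII, at least 37.5-fold higher on the MS-1 array.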

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

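All values here are from alternatives fixed in advance, except scaling to the poly-A controls, which was chosen after the data were seen. List medians are relative to all measured genes. Over all alternatives, 308 of 324 list medians moved by less than the 0.49 between probe sets, 15 moved further and 1, of a list outside the random range, reversed. The poly-A scaling and the centring shift all ratios equally and could not move these medians. The 0.49 is the error of 1 gene, so a list could lose most of its median and be counted with the 308, as Hox and positional did (0.53 to 0.11). Of 1384 ratios of named genes, 956 moved by less than 0.49, 424 moved further and 4 reversed. Only genes at least 2-fold apart in the main processing could be counted as reversed. Smaller ratios that changed sign, such as those of Vcam1 and Ccl2 when scaled to the poly-A controls, are not among the 4. That scaling shifts every ratio by 0.51, so all 155 measured named genes count as moved under it. Of the 20 lists outside the random range, 13 moved by over 1.5 times in at least 1 alternative. Of the 16 lists within the random range, 14 moved by over 1.5 times and 2 of the 308 changed sign (epithelial, to 0.046 with background doubled, and G2 and mitosis, to 0.013 in the mean over probe sets). With 2-fold and 8-fold thresholds, 1896 and 343 genes were higher on the SVEC4-10 array and 1498 and 279 on the MS-1 array. With no background floor, 888 genes were at least 4-fold higher on the MS-1 array and 1031 on the SVEC4-10 array, and the medians were -5.86 (pan-endothelial) and 3.51 (mesenchymal). Scaling to the poly-A controls gave 836 genes higher on the MS-1 array and 493 on the SVEC4-10 array, since every ratio shifts. With background doubled, the medians were -4.50 (pan-endothelial), -1.72 (arterial and Notch), 0.27 (strain-variable) and 0.054 (coagulation and complement, reversed). With background at the 40th percentile, arterial and Notch was at -0.34. Both background settings change which genes are measured. With the probe set of smallest ratio, the medians were -4.13 (pan-endothelial), -0.98 (sinusoidal), 0.0022 (chemokines), 1.55 (mesenchymal) and 0.34 (TGF-beta and BMP), and 3 genes reversed: Ndn (0.11), Hddc3 (-0.16) and Cxcl12 (-0.72). Cxcl12 also reversed in the mean over probe sets (-0.48), and for these 3 genes the cause was not tested. No paired analysis was possible because each line has 1 array. Signal over background limits all folds against it, which are lower bounds.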

Other observations

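The tests on the endothelial, interferon and sterol patterns, and the genes named here outside the fixed rule, were chosen only after the results were seen, except that the second mesothelial, fibroblast and smooth muscle lists were written after the main lists had been seen but before their own values were looked at.

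Tfrc, the transferrin receptor that takes up iron, had signals of 1573 and 344 and was 4.58-fold higher on the MS-1 array, and 3 separate control probe sets for it were 5.08-fold higher there. Slc40a1, the iron exporter ferroportin, was at least 12.5-fold higher on the SVEC4-10 array. Bnc1, a zinc finger protein, had a signal of 2746 on the SVEC4-10 array and was at least 169-fold higher there, Gpm6a at least 73.1-fold and Gata4 at least 10.4-fold. Msln, mesothelin, had signals of 21.4 and 1311, a 61.2-fold difference. Of 14 measured genes in the second mesothelial list, 5 were also above background on the MS-1 array, and the most abundant, Cpe, had signals of 3122 and 4574. Calb2, a mesothelial marker, was among 3 of the 17 listed genes that were not above background on either array and do not enter the median, and the keratins Krt18 and Krt19, also made by mesothelium, were 8.21-fold and at least 6.85-fold higher on the MS-1 array. Krt7, another simple epithelial keratin, went the other way and was at least 12.5-fold higher on the SVEC4-10 array. In the second fibroblast list, 6 of 16 genes, among them Pi16, Mfap4 and Scara5, were not above background on either array, and in the second smooth muscle list 4 of 14, among them Myocd, Kcnmb1 and Casq2, while Ppp1r12b was 2.39-fold higher on the MS-1 array. With these genes counted at background, the medians of the mesothelial, fibroblast and smooth muscle lists were 1.13, 0.11 and 0.33. Every gene at background on both arrays gets a log2 ratio of 0.11, set by the background levels. The fibroblast median of 0.11 is that value.

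On the array labelled SVEC4-10, 29 of 44 measured pan-endothelial genes were at background and the others were above it. This low endothelial signal, beside high mesenchymal genes, is hard to explain by a failed array. A general loss of signal would take genes of equal brightness to background, but of 1564 other genes at least as bright on the MS-1 array as the median pan-endothelial gene, 1.47% were at background on the SVEC4-10 array, against 17 of 22 pan-endothelial genes, and degraded RNA would shift 3'/5' ratios, which differed 1.04-fold. A minority of other cells in an endothelial culture like that of MS-1 would leave most endothelial signal in place, but the pan-endothelial median was -5.16. That ratio is to MS-1, so it cannot decide on other cells in a line with low endothelial genes of its own. Second marker lists shared 0 genes on the array with the main lists. Markers such as Dcn, Col1a1, Tagln and Wt1 were therefore not among them, and the list medians do not rank the cell types. The medians were 1.66 for mesothelial genes (9 of 14 at least 2-fold higher on the SVEC4-10 array, with Msln, Rspo1 and Ildr2 highest, percentile 100 of the random lists), 0.95 for fibroblast genes (5 of 10, percentile 99.1) and 0.53 for smooth muscle genes (4 of 10, percentile 97.3). Mesothelial-like cells may account for part of the pattern, although Calb2, Krt18 and Krt19 were not higher, while Krt7 was at least 12.5-fold higher. The fibroblast and smooth muscle explanations stay open, since their medians lay between the bounds of 0 and 1 set for a decision. With the genes at background on both arrays counted, these medians were 0.11 and 0.33, where 0.11 is the ratio given to any such gene. Loss of endothelial identity in this line, a culture of other cells and a wrong label all remain open, since 1 array stands for the line.

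The higher interferon-response genes on the array labelled SVEC4-10 are unlikely to come from leukocytes, since 0 of 10 measured leukocyte genes were at least 2-fold higher there. Scaling to the poly-A controls, which lowers every ratio by 0.51, gave the lowest list median over the scalings, 1.80. That shift is smaller than the list median of 2.32, and larger errors of scale were not tested. A difference between the lines or their strains of origin, an infection or a response to culture conditions could each give the pattern, and none was tested.

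A larger sterol supply from 10% serum, against 5%, would lower the sterol synthesis genes, so it would not by itself give their median of 1.59. Sterol in the medium was not measured, and serum cannot be told apart from the line, so a role of serum sterol is not excluded. Proliferation genes showed no difference of that size, with an S phase median of 0.23 (percentile 97.8 of the random lists) and a lower mitotic median. Growth rate was not measured, so faster proliferation is not excluded. Scaling to the poly-A controls, which lowers every ratio by 0.51, gave the lowest sterol median over the scalings, 1.08. That shift is smaller than the median of 1.59, and larger errors of scale were not tested. A difference between the lines, another effect of the serum, which cannot be told apart from the line, or the density or feeding of the cultures may remain as the cause and was not tested.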
